A study of Mus musculus with 2 samples.

How the data were processed

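Whole-genome bisulfite libraries of 2 mouse embryonic fibroblast lines, 1 wild type and 1 lacking Gadd45a and Ing1, were analysed from per-cytosine tables. Bisulfite converts unmethylated cytosine so that it is read as thymine, and the share of cytosine reads at a site gives its methylation. Per the labels' protocols, genomic DNA was fragmented by ultrasound, ligated to methylated adapters, size-selected and converted with a commercial bisulfite kit. Per the submitters' processing notes, FastQC, Bismark 0.9.0 and Bowtie 0.12.9 were used and the builds named are mm9 and NCBIM37. The deposited values are whole-number counts of methylated and unmethylated calls for each cytosine of a CpG on each strand, with no normalization, and the authors' tables for both libraries list the same 42649578 cytosines. Removal of duplicate reads, trimming and quality filters are not given in the sources used here. If duplicates were kept, calls at a site are less independent than the tests assume. Calls at neighbouring CpGs of 1 read are also not independent, with or without duplicates, and the tests count each of them. The tables carry no header. The methylated column was taken as the one that holds about 74% of calls, the usual bulk of a mammalian genome.

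Both cytosines of a CpG were joined to 1 site, giving 21324789 sites on chromosomes 1 to 19 and X. The WT library had a mean of 50.5 and the DKO library of 44.2 calls per site, a ratio of 0.876. Calls were uneven, since 0.01% of sites held 15.4% of calls in WT and 16.2% in DKO. The most covered site, on chromosome 2 at 98507306, had 11185986 and 10446771 calls. Alignments to a reference that lacks most copies of a repeat collect at such sites, so shares were also computed without the 0.1% of sites with most calls.

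Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. Global and per-chromosome levels were shares of calls with 95% Wilson intervals, and means over sites used at least 5 calls in both libraries. Windows of 1000 bp with at least 3 CpGs and 20 calls in each library were tested with a two-sided Fisher's exact test on methylated and unmethylated calls, using the chi-square test of the same table above 20000 calls. P-values were adjusted by Benjamini-Hochberg over all windows tested, and a window was called at an adjusted p of at most 0.05 and a difference of at least 20 percentage points. Domains of 100 kb needed 500 calls in each library. With 1 library per genotype, the same window test between the strands of 1 library served as a measure of technical spread within it. A shift shared by both strands of a library is outside that measure. The procedure was tested on simulated calls for the 52971 windows of chromosome 19. It called 20 of 50 windows changed by 20 percentage points, 48 of 50 changed by 30, 50 of 50 changed by 40, none of 50 changed by 10, and 2 unchanged windows. The simulated calls held counting error only, which was smaller than the spread between strands. These rates therefore do not give the error or power in the real data.

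Long segments with base variants were sought after the data were examined. A site was fully low when 1 library had at most 5% and the other at least 70% at 15 or more calls in each, and partly low at 30 to 55% against at least 90% at 20 or more calls. Bins of 1 Mb with at least 5 fully low or 15 partly low sites were joined across at most 6 Mb. Sites with no call on 1 strand and at least 10 on the other were counted separately. Stretches without calls were runs of at least 10 CpGs at 0 calls in 1 library and a mean of at least 10 in the other.

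Low-methylated regions were runs of at least 4 CpGs whose level, averaged over both libraries and smoothed over 3 CpGs, was under 50%, with steps of at most 500 bp. Runs with 30 or more CpGs were called CpG-rich, and those under 10% over at least 5000 bp valleys. Clusters were runs of at least 15 CpGs over 200 bp with steps of at most 50 bp. Regions and cluster levels came from plus-strand calls and differences from minus-strand calls, so that the same calls did not both choose and measure an element. These elements were also defined after the data were examined.

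Named regions followed a rule fixed before the data were examined. Called windows of 1 direction at most 1 kb apart were joined, and the 5 regions with most called windows and the 5 with the largest difference among regions of at least 2 windows were taken in each direction. Alternatives covered coverage minimums, strands, window size, thresholds, depth, centring, variance and sites with extreme coverage. No genome sequence of build mm9 was used, and the gene table at hand is of assembly GRCm38.p6, whose coordinates were not converted or printed. Promoters, gene lists, gene features, C/EBP motif CpGs and named genes of the original plan were therefore not analysed here, and coverage of Gadd45a and Ing1 was replaced by a search for stretches without calls. Their chromosomes are stated from general knowledge.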

Results

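Whole-genome bisulfite sequencing was used to read cytosine methylation in mouse embryonic fibroblasts from 2 male embryos of embryonic day E15.5, cultured for 4 passages. One line was wild type (WT) and the other lacked both Gadd45a and Ing1 (double knockout, DKO). Gadd45a is a small stress-induced nuclear protein linked to active DNA demethylation, and Ing1 is a plant homeodomain protein that binds trimethylated lysine 4 of histone H3. The comparison asks where DNA methylation differed when both were missing. There was 1 library per genotype, so no difference below has a replicate check, and each test on reads compares these 2 libraries and not the genotypes. Both libraries covered the same 21324789 CpGs on 20 chromosomes. The WT library held 1076410374 methylation calls, a median of 44 per CpG, and the DKO library 943461244, a median of 38. At least 5 calls were present at 97.3% of CpGs in WT and 97.1% in DKO. All positions are those of mouse build mm9, and percentages are methylated calls as a share of all calls.

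The DKO library had no calls over 2 CpG-rich stretches of a few kilobases, on the chromosomes that carry the deleted genes. On chromosome 6, which carries Gadd45a, none of the 131 CpGs from 66986306 to 66989808 had a DKO call, while WT had 4045 calls there with 26.2% methylated. On chromosome 8, which carries Ing1, none of the 76 CpGs from 11561067 to 11564421 had a DKO call, while WT had 2687 calls with 93.4% methylated. A count of 0 allows at most 3 calls. DKO coverage was present on both sides, with a median of 49 calls per flanking CpG on chromosome 6 and 32 on chromosome 8. In total DKO had 45 stretches of at least 10 CpGs without calls and WT had 108. Of the DKO stretches 43 lay in the DKO segments of chromosomes 6 and 8 described below, some with more CpGs than these, such as 204 on chromosome 8 from 15449607 to 15480556, so a position on these chromosomes does not set the 2 apart. Outside the segments were the chromosome 6 stretch above and one of 20 CpGs on chromosome 3 from 77975179 to 77977906, where WT had 583 calls. The 2 were singled out as the DKO stretches without calls that had at least 50 CpGs at 20 or more per kb, against 8.27 per kb for the genome, and WT had 2 such stretches elsewhere. This density rule was chosen after the values were seen, and a stretch of 56 CpGs on chromosome 6 from 54925463 to 54928371, at 19.25 per kb, fell just short of it. No gene annotation of build mm9 was used, so whether these stretches lie in the targeted genes was not tested.

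**Figure D1:**
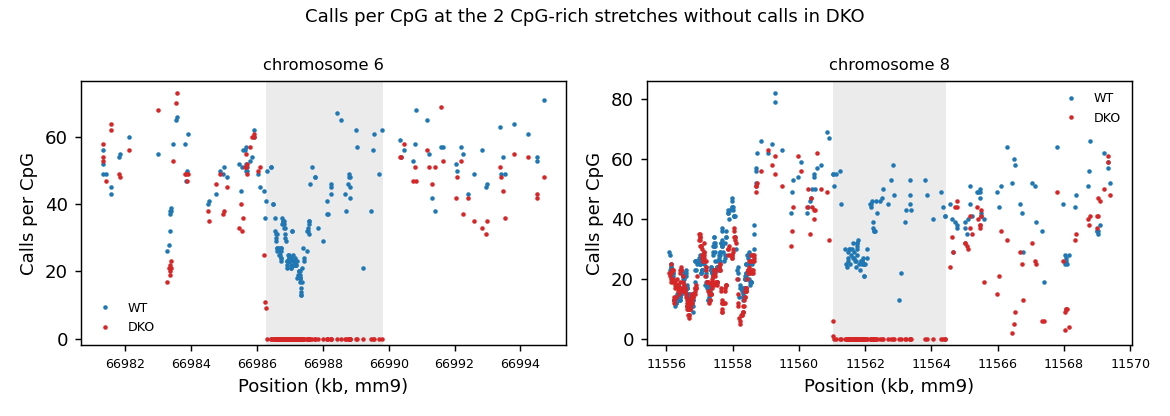
Methylation calls per CpG (vertical axis) against position in kb of build mm9 (horizontal axis) around the 2 CpG-rich stretches without DKO calls, with WT in blue, DKO in red and the stretch shaded. Inside the shaded stretches all 131 CpGs on chromosome 6 and all 76 on chromosome 8 had 0 DKO calls, while WT CpGs were covered.

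Methylation over the whole genome differed by a fraction of a percentage point. In WT 74.0022% of calls were methylated (95% Wilson interval 73.9996 to 74.0049%) and in DKO 74.2173% (74.2145 to 74.2201%), a difference of 0.215 percentage points. The intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The mean over CpGs with at least 5 calls in both libraries was 71.0% in WT and 71.2% in DKO, and site levels correlated across CpGs with r = 0.937, where CpGs are not independent replicates. CpGs over 80% methylated made up 52.3% of sites in WT and 51.9% in DKO, those over 50 and up to 80% made up 29.1% and 29.7%, and those up to 10% made up 8.34% and 8.17%.

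The difference was spread over most chromosomes. DKO was higher on 18 of 20, with a median difference of 0.205 percentage points. Chromosome 7 had the largest difference, from 70.02% in WT to 70.82% in DKO, and chromosomes 6 (73.2% and 72.8%) and 12 (75.29% and 74.97%) were lower in DKO. With the 4 segments described below and the 0.1% of sites with most calls left out, chromosome 7 still differed by 0.707 percentage points, higher in 61 of 65 bins of 2 Mb. Under the same restriction chromosome 6 was lower in 49 of 68 bins and chromosome 12 in 39 of 60.

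In 4 long segments the libraries differed CpG by CpG. In DKO, 3854 CpGs had at most 5% methylation while WT had at least 70%, and 98.6% of them lay in only 2 segments. These were chromosome 6 from 49693049 to 63718270, with 2133 such CpGs, and chromosome 8 from 11076786 to 24883900, with 1668. The chromosome 8 segment contains the CpG-rich stretch without DKO calls described above, and the chromosome 6 segment ends before the other. WT had 1129 such CpGs in the opposite sense, 93.3% of them in 2 segments of its own, nearly all on chromosome 7 from 6606620 to 25566043, with 1024. The other WT segment, chromosome 8 from 30658178 to 44473992, had 29 fully low CpGs but 1498 at 30 to 55% where DKO was at least 90%, against 9 in the opposite sense. CpGs with no call on 1 strand and at least 10 on the other were also concentrated there, at 73.1 per 10000 inside the DKO segments and 0.235 per 10000 outside in the DKO library. The corresponding WT rates were 42.4 and 0.064 per 10000. The labels give the same C57BL/6N background for both lines. Because a base that differs from the reference can be read as an unmethylated cytosine, counts below are given with and without these segments.

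**Figure D2:**
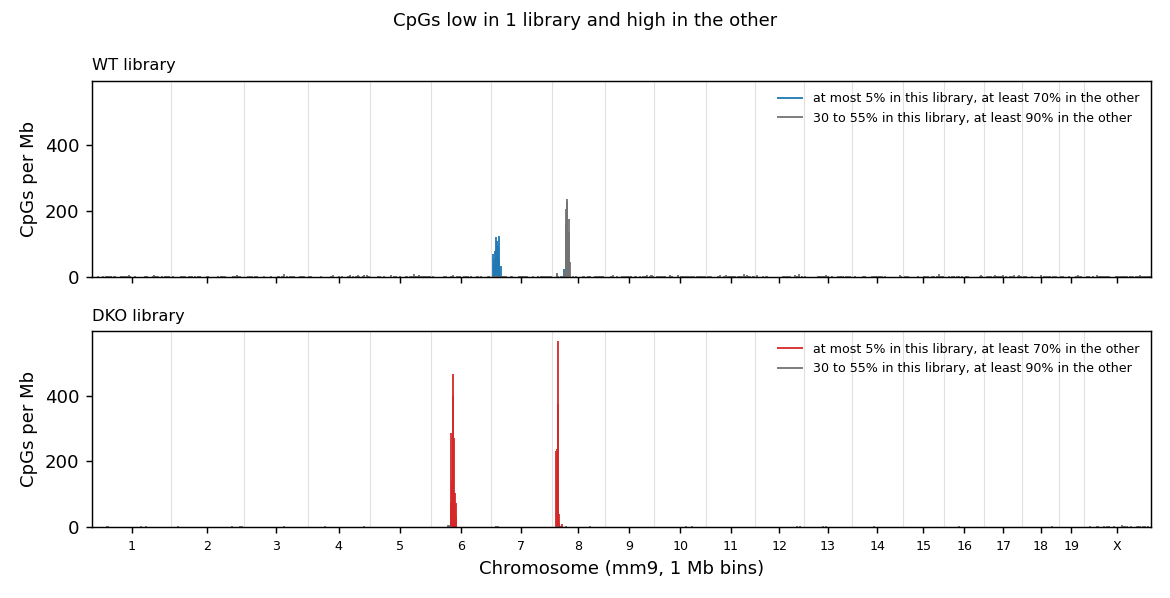
Number of CpGs per 1 Mb bin (vertical axes) along chromosomes 1 to 19 and X of build mm9 (horizontal axis) that were at most 5% methylated in the named library and at least 70% in the other (coloured), or 30 to 55% in the named library and at least 90% in the other (grey). The WT library has its peaks on chromosomes 7 and 8, and the DKO library on chromosomes 6 and 8.

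Outside these segments, windows that differed were mostly more methylated in DKO. Of 2165093 windows of 1 kb outside the segments, 2221 were at least 20 percentage points higher in DKO and 485 at least 20 lower at a Benjamini-Hochberg adjusted p of at most 0.05 (two-sided Fisher's exact test on calls). These counts depended on the settings, with 7850 and 1422 at 500 bp and 267 and 109 at 2000 bp. At 1 kb the lower count fell to 283 at an adjusted p of 0.01 and to 151 with the variance inflated by the spread between strands. At the settings first named, 82.1% of the called windows outside the segments were higher in DKO, while 95.6% of the windows tested there lay within 10 percentage points. Inside the segments, 998 of 46985 windows were higher and 1410 lower, which gave 3219 higher and 1895 lower for all 2212078 windows. The called share was 512.5 per 10000 windows inside and 12.5 outside. Joined where they touched or lay at most 1 kb apart, the called windows outside made 2151 regions higher in DKO, with median levels of 45.6% in WT and 69.4% in DKO, and 475 lower, with 75.5% and 52.2%.

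The excess of higher windows appeared on each strand between the libraries and not between the strands of 1 library. A shift of a whole library, technical or biological, would not appear between its strands. Within the WT library, the same test between plus-strand and minus-strand calls called 4978 windows outside the segments, 2412 higher and 2566 lower on the minus strand. Within DKO it called 5255, with 2472 higher and 2783 lower on the minus strand. Between opposite strands of different libraries it called more, 11149 for WT plus against DKO minus (6644 higher and 4505 lower in DKO) and 11496 for WT minus against DKO plus (7401 and 4095). Between the libraries on the same strand, plus-strand calls gave 3616 higher and 1228 lower in DKO, a total of 4844, and minus-strand calls 3759 and 1276. Windows called higher in DKO on the plus strand had a median difference of 11.9 percentage points on the minus strand. There 88.0% had the same sign and 57.5% were higher by at least 10. For windows called lower the median was −3.48 percentage points, 66.8% had the same sign and 21.5% were lower by at least 10. Over all 2138235 windows compared, differences on the plus and minus strands correlated with r = 0.135. Binomial draws from 1 pooled level per window, which hold counting error only, called 0 windows, so counting error was smaller than the spread between strands.

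In percentage points, the median difference of windows was largest at intermediate levels. Outside the segments, windows with a mean level of 30 to 40% had a median difference of 1.42 percentage points (quartiles −2.56 to 5.62), and 191 were called higher against 21 lower. Windows of 80 to 90% had a median of −0.201, with 34 called higher and 21 lower. Windows under 10% had a median of 0.081, and a mean level that low rules out a difference of 20 percentage points. On chromosome X, 19.09 windows per 10000 were higher in DKO and 9.63 lower, whereas no autosome exceeded 11.3 and 2.78. Both embryos were male, with 1 copy of X, and depth was not matched. Among regions named below, 16 CpGs on X from 89924001 held 380 WT calls, against 769 for 16 on chromosome 1 from 92738001. Fewer calls widen differences in both directions, so these rates do not show that X differed more.

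CpG-poor low-methylated regions, short stretches of reduced methylation of the kind found at distal regulatory elements, were more methylated in DKO. These regions were found on plus-strand calls of both libraries and measured on minus-strand calls. Of 103672 regions outside the segments, with a median of 6 CpGs and 391 bp, 60.8% were higher in DKO, and the pooled level was 26.6% in WT and 29.0% in DKO. The median difference was 2.08 percentage points (SD over regions 9.11), and 3022 regions were called higher against 520 lower. It was above 0 on all 20 chromosomes, from 1.03 on chromosome X to 2.30 on chromosome 16. Sequence 2 to 3 kb outside the regions had a median difference of 0.003 and 50.01% higher. Of the 196239 flanks, 472 were called higher and 141 lower, so the called flanks also leaned towards higher levels in DKO. The median difference rose with the level of the surrounding 100 kb, from 0.594 percentage points where that was under 60% to 3.41 where it was at least 80%.

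CpG-dense elements differed in both directions. The 16643 CpG-rich low-methylated regions, with at least 30 CpGs, had a median difference of 0.334 percentage points, and 59.2% were higher in DKO, a share near that of the CpG-poor regions, while their pooled level was 6.10% in WT and 6.00% in DKO. Over all 16643, the median level of 5.01% in WT left little room for a fall of 20 percentage points, though not for a rise. At 20 percentage points 0 passed as higher and 3 as lower, and at 10 percentage points 77 passed as higher and 66 as lower. In 448 methylation valleys, which are low-methylated stretches of at least 5 kb often found around developmental genes, the median difference was −0.351, with 64.7% lower in DKO. CpG clusters under 10% methylated, of the kind found at CpG island promoters, stood at 0.965% in WT and 0.983% in DKO over 19877 clusters. The 1793 clusters at 10 to 35% had pooled levels of 18.2% in WT and 12.7% in DKO, a difference of −5.49 percentage points, while their median difference was 0.081, with 19 called higher and 12 lower. Pooled levels weight clusters by calls, and 11 very deep windows described below fell from 16.9% to 4.39%. With each cluster weighted equally, the mean difference was −0.0026 percentage points, so the pooled fall came from clusters with many calls. Whether those 11 windows set the pooled levels here was not tested. The 1432 clusters at 35 to 65%, the range in which imprinted control regions lie, had pooled levels of 51.1% and 51.7%, with 48 called higher and 31 lower, while their median difference was −0.269 percentage points and 51.7% of them were lower in DKO. Of 20937 clusters at 65% or more, 63 were called higher and 24 lower.

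**Figure D3:**
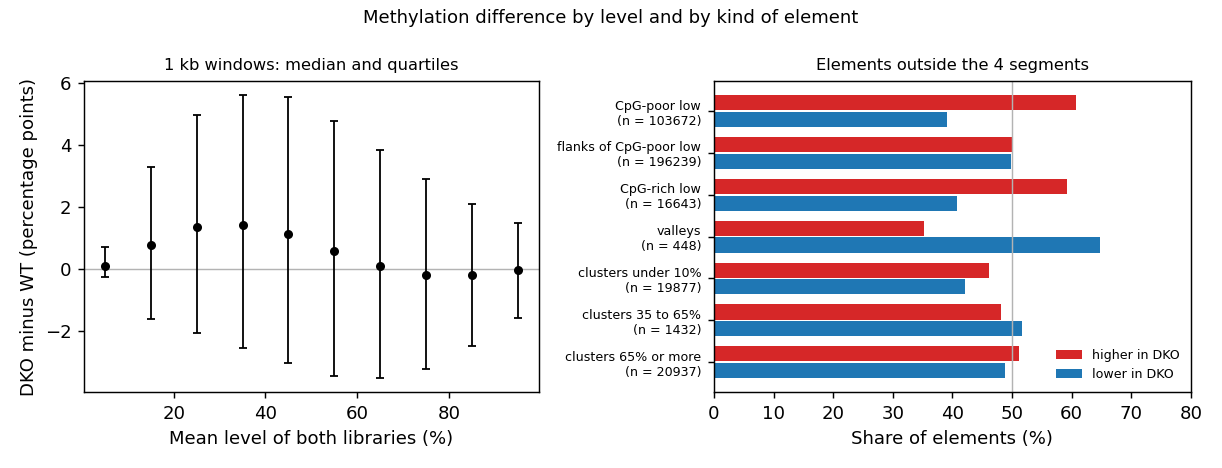
Left, DKO minus WT methylation in percentage points (vertical axis; points are medians over 1 kb windows and bars the quartiles) against the mean level of both libraries in percent (horizontal axis). Right, share of elements in percent (horizontal axis) that were higher (red) or lower (blue) in DKO for 7 kinds of element, with the number of elements. The largest median, 1.42 percentage points, is at 30 to 40%, and 60.8% of CpG-poor low-methylated regions are higher in DKO.

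By number of neighbouring CpGs within 100 bp, the difference was −0.115 percentage points for CpGs without neighbours, 0.641 for those with 7 to 10 and 0.609 for those with 11 to 15. The densest class, with 16 or more, was 5.39% in WT and 4.79% in DKO, a difference of −0.599 percentage points that turned to 0.064 without the 0.1% of sites with most calls. The median difference of 25616 windows of 100 kb was 0.108 percentage points (SD over windows 1.22), and 89 were at least 5 higher and 67 at least 5 lower in DKO. Outside the segments these counts were 11 and 8. Windows of 100 kb under 60% methylated, which include partially methylated domains, had a median difference of 0.071.

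The rule for named regions took 20 regions, of which 19 lay inside the 4 segments. Among regions of at least 2 windows, the largest fall was on chromosome 6 from 56804001 to 56806000, from 94.0% in WT (521 calls) to 30.6% in DKO (124 calls), and the largest rise on chromosome 7 from 12676001 to 12678000, from 14.1% (128 calls) to 67.6% (299 calls). Without CpGs of the kind that mark the segments, these differences were −33.4 and 42.0 percentage points. The region outside was on chromosome X from 166428001 to 166437000, where 9 windows held 318 CpGs. It rose from 42.3% (95% Wilson interval 41.67 to 42.97%) in WT to 74.1% (73.7 to 74.5%) in DKO, and calls rose with it, from 22422 to 44045. The whole DKO library had fewer calls per site than WT, at a ratio of 0.876. A change in the number of sequence copies collected at these positions was therefore not excluded as a source of the higher level.

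The same rule outside the segments, added after the data were seen, gave further regions. Those higher in DKO included chromosome 6 from 4458001 to 4462000, which rose from 39.3% to 69.9%, and chromosome 17 from 40508001 to 40510000, from 35.9% to 81.2%. Chromosome 5 from 110335001 to 110337000, with 96 CpGs, rose from 57.8% (56.0 to 59.6%) to 91.3% (89.8 to 92.6%). Calls there fell from 2875 in WT to 1578 in DKO, further than the ratio of 0.876 between the libraries. Fewer unmethylated copies in DKO, in place of a gain of methylation, were therefore not excluded. Chromosome 1 from 92738001 to 92740000 rose from 33.2% to 67.2%. Chromosome 11 from 94807001 to 94811000 rose from 48.5% to 72.2%, chromosome 3 from 138316001 to 138319000 from 47.9% to 69.3%, and chromosome 10 from 67588001 to 67591000 from 40.4% to 60.5%. On chromosome X, the region from 89924001 to 89926000 rose from 29.5% to 60.7%.

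Among the regions lower in DKO, chromosome 18 from 30426001 to 30429000 had 135 CpGs and changed from 68.6% (66.8 to 70.4%) to 33.1% (31.2 to 35.1%). Chromosome 14 from 54916001 to 54918000 changed from 73.2% to 48.5%, and chromosome X from 55269001 to 55271000 from 52.6% to 26.2%. Chromosome 16 from 36769001 to 36771000 changed from 86.0% to 62.7%, with −13.2 percentage points on the plus strand and −31.5 on the minus strand. Chromosome 2 from 57074001 to 57076000 changed from 82.4% to 54.2% on only 153 and 120 calls, with −44.8 on the plus strand and −4.95 on the minus strand. On chromosome 8, the regions from 25405001 to 25407000 (49.2% and 21.0%) and from 25770001 to 25775000 (77.3% and 46.3%) lay within 1 Mb of the end of the DKO segment. The 1 Mb bin of these regions held 4 fully low CpGs in DKO, under the 5 that a segment bin needs, and 11 read on 1 strand only, so base variants were not excluded there. Each called window of these regions passed the adjusted p of 0.05. Levels are for the called windows, and some regions also span windows that were not called. Which genes the regions belong to was not analysed here.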

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

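The tests in this part were chosen after the stretches of low CpGs were seen, and for the partly low CpGs of WT chromosome 8 what each explanation predicts was set down before the test was run. At CpGs with calls on 1 strand only, the missing strand is not a methylation value, though the other strand's calls entered the levels above. Such CpGs stood out in 4 segments against the other library at the same positions. The DKO library had 695 in its chromosome 6 segment and 652 in its chromosome 8 segment, where WT had 0. The WT library had 522 in its chromosome 7 segment, where DKO had 0, and 145 in its chromosome 8 segment, where DKO had 1. In that last segment all but a few lay at its start, 34 and 111 in the WT bins of chromosome 8 at 30 and 31 Mb, ahead of the partly low CpGs.

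Low CpGs in these segments could reflect either lost methylation or another haplotype. In the 3 segments of fully low CpGs, 1869 CpGs lacked calls on 1 strand in the affected library and 0 in the other. In each segment this was at least 245 times the frequency outside, taken over all CpGs inside and over covered CpGs outside. Lost methylation alone would not give this, and other bases on a haplotype would. In the partly low stretch of WT chromosome 8 from 33 to 45 Mb, CpGs at 30 to 55% on 1 strand only were 15.2 times as frequent as outside, against a loss on 1 of the copies as the whole account. At these 227 CpGs the other strand, at 90% or more, had a median of 0.615 times the calls, against 1.40 times outside, which is consistent with another haplotype on 1 of the copies, as a hypothesis. Whether part of the difference in the segments is methylation stays open, since 1059 of 2408 called windows there remained called without the variant-like CpGs.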

How the results depend on the processing

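No paired analysis was possible because each genotype had 1 library. The settings outside the segments, without variant-like CpGs, without the most covered sites for the density classes, by mean over sites, and for CpG-poor regions were added after seeing the data. The global difference of 0.214 percentage points at sites with 5 calls stayed positive under 8 alternatives. It was 0.203 with a minimum of 10 calls, 0.247 on the plus strand, 0.177 on the minus strand, 0.205 without the 0.1% of sites with most calls and 0.159 as a mean over sites. The densest CpG class was −0.756 with 250 bp on each side and turned to 0.064 without the most covered sites, so those sites carried its sign. CpG-poor regions had a median of 2.19 with the strands exchanged and 1.94 under a level of 30%.

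Windows called higher and lower in DKO changed with the settings; the values for all windows come first and those outside the segments after them. Windows of 500 bp gave 9317 and 3419, and 7850 and 1422. Windows of 2000 bp gave 704 and 779, and 267 and 109. A difference of at least 10 percentage points gave 26611 and 11319, and 23827 and 8575. At least 30 gave 512 and 689, and 165 and 39. Outside the segments, plus-strand calls gave 3616 and 1228, and minus-strand calls 3759 and 1276. There, windows lower in DKO numbered 283 at an adjusted p of 0.01 and 151 with the variance inflated by the spread between strands. Without variant-like CpGs, 904 of all windows were lower, and the higher share of all called windows went from 62.9% to 75.2%. Outside the segments that share ranged from 71.0 to 91.5% over 14 alternatives, while for all windows it was below 50% at 2000 bp and at 30 percentage points, 47.5 and 42.6%. All 35 named regions kept their sign on both strands and without variant-like CpGs. The same calls had chosen these regions for large differences, so a kept sign is weak evidence. Without those CpGs 16 differences, all in the segments, moved beyond counting error and 12 shrank by over 1.5 times. Over all windows between its ends, chromosome 8 from 16247001 to 16258000 went from −21.4 to −3.27 percentage points, within counting error of 0, chromosome 7 from 19481001 to 19489000 from 20.6 to 4.20, and chromosome 8 from 15164001 to 15173000 from −26.9 to −8.05. Thinning WT to the depth of DKO gave 2292 and 500 outside the segments. On simulated chromosome 19 calls the test recovered 40% of changes of 20 percentage points, its own limit, and 96% of changes of 30. Those calls held counting error only, and other depths were not simulated. Alternatives for promoters, gene lists, gene features and C/EBP motif CpGs were not run, since no annotation of the build was used.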

Other observations

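The tests in this part were chosen after the results were seen, although the calls between the libraries on the same strand came from planned settings. Outside the 4 segments, 4 stretches had under 1 WT call per CpG on average, with usual WT coverage within 20 kb. On chromosome 16 from 6115959 to 6138079, WT had 2 calls over 187 CpGs and DKO 7573, a mean of 40.5 per CpG. On chromosome 8 from 116306709 to 116325385, WT had 57 calls over 218 CpGs and DKO 8826. Both had WT medians of 47 calls per CpG within 20 kb. On chromosome 7 from 116233971 to 116239033, WT had 0 calls over 36 CpGs and DKO 1599. On chromosome 8 from 28062088 to 28068230, WT had 18 calls over 58 CpGs and DKO 1419, a DKO mean of 24.5 per CpG against a median of 36 within 20 kb. A longer stretch on chromosome 7, from 27637202 to 27740405, was low in both, with a mean of 3.53 calls per CpG in WT and 17.9 in DKO, and 390 of its 963 CpGs were in runs without WT calls.

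In the DKO library, chromosome 8 from 15424549 to 15480556, inside its segment, had 368 calls over 461 CpGs where WT had 17363. The WT chromosome 8 segment was 72.1% methylated in WT and 76.1% in DKO from 33 to 45 Mb. The log2 ratio of DKO over WT calls, minus its median over all 1 Mb bins, was 0.22 from 34 to 44 Mb. That centred ratio was 0.00 over the next 10 Mb. Without centring, mean calls per CpG were nearly equal in both libraries from 34 to 44 Mb. Over the next 10 Mb WT had more calls per CpG than DKO, and more than WT had from 34 to 44 Mb. By the bases beside the CpG, the difference outside the segments ran from −0.038 percentage points for GCGC to 0.537 for CCGG.

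Higher methylation in DKO at low and intermediate levels may come from less complete conversion, but that would need a rise of 3.36 percentage points at unmethylated sequence, and 12 unmethylated windows of at least 20000 calls differed by −0.042 (SD 0.131). For base variants outside the segments, the share of called windows that were higher in DKO was 82.4% without variant-like CpGs and 82.1% with them. That filter takes out only CpGs past the cutoffs used to find the segments or read on 1 strand only. It therefore cannot exclude other base variants. The spread between strands of 1 library, with 4978 calls within WT and 5255 within DKO, falls short of the 11149 and 11496 calls between opposite strands of WT and DKO. Calls between the libraries on the same strand were 4844 and 5035. Both were below the 5255 within DKO, and the 5035 was above the 4978 within WT. In direction, 59.6% and 64.4% of the opposite-strand calls and 74.6% of the plus-strand calls were higher in DKO. The more frequent direction within WT and DKO held 51.55% and 52.96%. A shift of a whole library is shared by both its strands and cancels in the within-library test. That test therefore cannot decide where the direction comes from. The genotype cannot be told apart from other differences between 2 embryos, cultures or library preparations, since there was 1 library per genotype.

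A further 11 windows of at least 20000 calls on 5 chromosomes, 6 of them on chromosome 17 from 39980001 to 39986000, were lower in DKO, at 16.9% in WT and 4.39% in DKO. In the window on chromosome 6 from 3151001 to 3152000, 22 of 44 runs of 5 CpG spacings recurred in the chromosome 17 stretch, and in the other 4 windows none did. Methylated copies may be fewer in DKO, or the same copies less methylated. Scaled to depth, unmethylated calls were 0.956 times those of WT and total calls 0.831 times. These cannot be told apart, because total calls pooled over 12 unmethylated windows were 0.853 times and over 55 methylated ones 1.07 times those of WT, and single windows of these ranged from 0.686 to 1.15.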
